A study of Anguilla anguilla with 8 samples.

How the data were processed

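Liver RNA of male European eels (Anguilla anguilla) was measured on 8 one-colour Agilent microarrays. Per the labels, each array held a pool of RNA extracted separately from the livers of 3 males, labelled with cyanine 3. There were 4 pools of sexually immature males, injected weekly for 140 days with 0.9% saline, and 4 pools of males brought to maturity by weekly injections of human chorionic gonadotropin (hCG) at 2000 IU per kg over the same period. The sample codes in the labels share no numbers between groups, so pools were numbered 1 to 4 within each group in the order of deposit, and the numbers pair nothing across groups. The labels do not say whether the pools of a group shared males. If they did, the p-values would measure a spread that is partly technical.

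The deposited scanner files give spot intensity on a linear scale. Per the file headers, the intensity values came from Agilent Feature Extraction 9.5.1.1, with background subtraction and with spatial and multiplicative detrending within each array. Per the series text deposited by the authors, slides were scanned at 5 µm resolution at a pair of sensitivity levels, and both images were read together. The files hold no normalization between arrays. Other columns deposited by the authors hold flags per spot, such as found, saturated, outlier and well above background, as set by the scanner software. The series text says that intensities were kept by a flag value without naming the flag. A table of processed intensity values deposited by the authors covers the same arrays, and how it was normalized is not given in the sources used here. Its columns were linear and had the same maximum of 334223. Their medians were 20.88, 20.95, 21.03 and 20.98 for immature pools 1 to 4 and 20.62, 20.76, 20.76 and 20.80 for mature pools 1 to 4. Each column ranked its found spots as the processed signal of its own array did, and best matched that array, so its rows and direction were settled. It was used as an alternative. Its exact normalization and its treatment of spots that were not found remain unknown.

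Each array held 15449 spots, of which 536 were controls and were left out. The other 14913 spots were 60-base probes with 14662 distinct sequences, whose names hold 13523 different identifiers, here called contigs. For all 14913 probes the gene name column repeated the probe name, the description read Unknown and the position read unmapped. None of the probe names matched the table of European eel genes used here (0 matches), so no probe was given a gene name. Planned tests per gene and of fixed gene lists, including markers of other cell types, were therefore not run. Under the rule fixed before the data were examined for files without gene names, the text names at most 2 probes that rose and 2 that fell. They are those with the largest fitted differences among the probes past the threshold.

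Processed signals were taken to log2, and the 75th percentile of the non-control probes of each array was subtracted. Outlier spots (24 over all arrays) were set to missing. Probes were tested if they were well above background on at least 3 of the 4 arrays of at least 1 group, which kept 8768 probes and left out 6145. Mature and immature pools were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05. Differences are given as mature minus immature on the log2 scale with their standard error (SE). Where a probe was not well above background on any array of a group, its fold is a lower bound. The bound sets the mean of the brighter group against the mean, over the dimmer group's arrays, of the higher of the probe's own signal and the lowest signal of any probe well above background. Tests of single values between groups are two-sided exact permutation tests over the 70 assignments of 4 of 8 pools, whose smallest p is 0.0286. Probes that shared a run of at least 20 bases on either strand were counted as 1 family. Tables were read with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

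The procedure was tested on simulated data with the real spread of the 8768 probes, in 5 runs with 200 changed probes each. It recovered 0% of probes changed by 1.5-fold, 19.4% at 2-fold, 81.7% at 4-fold and 94.2% at 8-fold. The false share of the calls was 3.96%, 5.55% and 3.98% at 2-fold, 4-fold and 8-fold. Without any change it called 0 probes in the 5 runs. The simulated noise was normal and independent between probes and arrays, without effects shared by the probes of an array. The false shares may therefore not hold for the real arrays. The number of arrays limits the precision.

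All arrays lay on 1 slide and were read in 1 scan, so slide and scan date could not be used as blocks. The immature arrays filled 1 of the 2 rows of the slide and the mature arrays filled the other, so row and group cannot be told apart. Alternatives fixed before the data were examined were quantile normalization, median scaling, normexp background correction with an offset of 50, the deposited table, other filters on dim probes, limma with trend and robust settings, array weights, and leaving out each pool in turn. Scaling to the spike-in controls, a spike-in curve, the slide column as a block, averaging of identical sequences, a second detection flag, and raising single spots not well above background to the floor of their array (the lowest signal of any probe well above background) were added after seeing the data. The correlation of S and AS probes over other splits of the arrays was also computed after seeing the data. For counts of probes above background in 1 group alone, leaving out each pool was also added after seeing the data.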

Results

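The data describe liver RNA of male European eels that were either immature or had been brought to sexual maturity with hCG, a hormone that acts through the luteinizing hormone receptor. European eels are not sexually mature as they leave fresh water, and captive males are matured with such injections. Each group comprised 4 pools of 3 males, and each pool was hybridised to 1 array. The study compared liver transcript levels of mature males with those of immature males. Of 14913 probes, immature pools 1 to 4 had 9298, 8915, 8777 and 8527 well above background. Mature pools 1 to 4 had 8062, 8938, 7595 and 8995. The share was 59.5% ± 2.16 in immature pools and 56.3% ± 4.59 in mature pools (SD, n = 4 each, two-sided exact permutation p = 0.314). No spot was saturated (0 on each array). On all 8 arrays, 7109 probes were well above background, and 4884 were so on none.

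Pools of the same maturity resembled each other more than pools of different maturity. Over the tested probes, the mean Pearson correlation was 0.971 for the 12 pairs of pools within a group, with a range from 0.962 to 0.982. It was 0.957 for the 16 pairs between groups, with a range from 0.937 to 0.963. The first principal component held 33.7% of the variance and separated the groups. Mature pool 3 had a mean correlation of 0.963 with the rest of its group, against 0.978 among the other mature pools. The closest pair, mature pools 2 and 4, had differences with an SD of 0.468 on the log2 scale, against up to 1.03 over all pairs. These SDs cover only the 7109 probes well above background on all arrays.

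Maturation under hCG went with changes in both directions in the liver. Of 8768 tested probes, 184 (2.1%) passed the limma test at an adjusted p of 0.05, 106 of them higher and 78 lower in mature males. By the fit, at least a 2-fold difference was reached by 92 higher and 69 lower probes, 161 together. Of the 184 probes, 22 had no array well above background in their lower group, so their folds are bounds. With these 22 at their bounds, 89 higher and 63 lower probes reached at least 2-fold and 17 higher and 18 lower probes at least 8-fold. The median was then 3.62-fold among the higher probes and 3.08-fold among the lower ones, against 3.87-fold and 3.42-fold by the fit. At least 1 spot of the lower group was not well above background in 28 higher and 27 lower probes. With all such spots at the floor of their arrays, 89 higher and 60 lower probes reached at least 2-fold. At least 8-fold was then reached by 12 higher and 16 lower probes, and the medians were 3.45-fold and 2.99-fold. The smallest fitted difference past the threshold was 1.71-fold, and the smallest adjusted p from limma was 0.000953. In all 184 probes the 4 mature and the 4 immature pools did not overlap, which selection at this threshold nearly requires. Non-overlap held for 1212 tested probes (13.8%), where chance gives 2.86% if arrays are interchangeable and probes are chosen without regard to group. The filter on dim probes counted detection within each group, which can raise this share by itself. The 2.86% is therefore not an exact reference. At an unadjusted p of 0.05 from limma, 1739 probes (19.8%) passed against 438 expected by chance. Other splits of the 8 arrays into 4 and 4 gave between 168 and 1000 such probes. A split with 2 immature pools on each side gave 985, so 438 understates what arrays can give apart from maturity. The 184 probes belonged to 168 sequence families, 94 higher and 74 lower. In 12 families more than 1 probe passed, 28 probes in all, and in none of these families (0) did the probes move in opposite directions. Changes were spread over the range of abundance. With the tested probes ordered into 4 sets of 2192 by mean level, 55, 32, 43 and 54 probes passed from the dimmest to the brightest set.

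**Figure D1:**
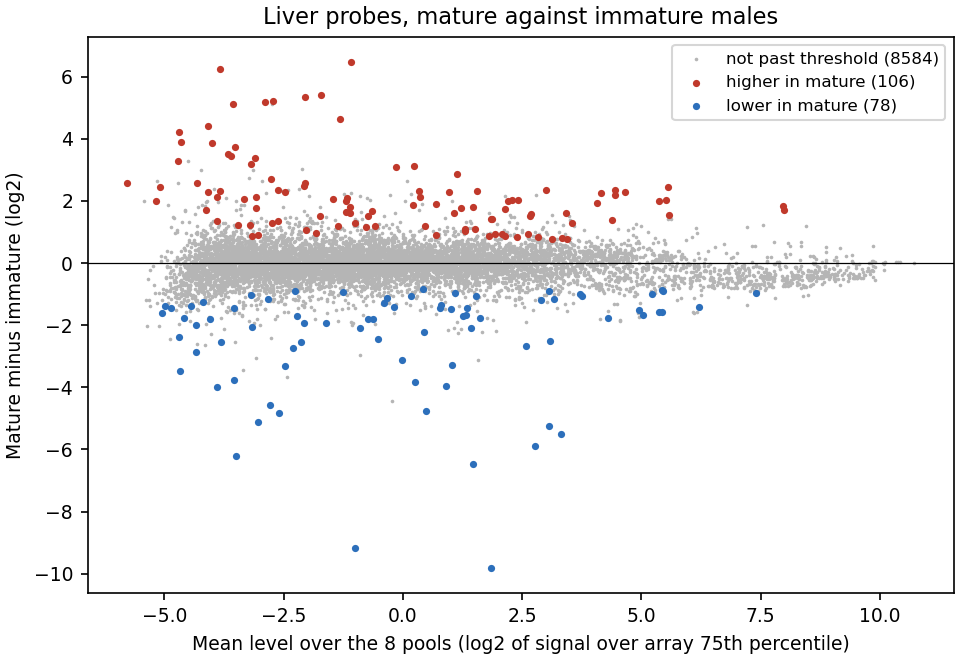
Each point is 1 of the 8768 tested probes, with its mean level over the 8 pools on the horizontal axis (log2 of signal over the 75th percentile of the array) and mature minus immature on the vertical axis (log2). Red points are the 106 probes higher and blue points the 78 probes lower in mature males past the limma threshold, which lie at all levels of abundance.

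The number of probes past the threshold depended on settings and on single pools. It was 80 when arrays were scaled to their spike-in controls and 503 with array weights, and leaving out 1 pool at a time gave 100 to 172. All arrays of a group shared 1 row of the slide, so row and maturity cannot be told apart. All mature pools and no immature pools received hCG, so effects of hCG itself and of maturity cannot be told apart either.

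Among the probes past the threshold, P_eeel_c19226 had the largest fitted rise in the main fit of all 8 pools. With array weights its fitted rise was 70.5-fold, below the 124-fold of P_eeel_rep_c58780. The level of P_eeel_c19226 was 2.15 ± 0.40 in mature and -4.32 ± 1.79 in immature pools (log2 relative to the 75th percentile, SD, n = 4 each). The difference was 6.47 (SE 0.76), or 88.6-fold, with an adjusted p of 0.0043 from limma. It was well above background on all 4 mature and on 3 immature arrays, and with the spot of immature pool 4 raised to the floor of its array the difference was 60.6-fold. It was 48.8-fold without immature pool 4 and 12.6-fold with normexp background correction. Its sequence is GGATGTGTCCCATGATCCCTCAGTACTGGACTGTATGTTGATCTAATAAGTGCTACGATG. The probe P_eeel_rep_c58780, with the sequence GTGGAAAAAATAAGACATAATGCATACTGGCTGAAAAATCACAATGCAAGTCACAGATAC, was well above background in all 4 mature pools and in 0 immature pools. Its level was -0.73 ± 1.98 in mature pools (SD, n = 4), at least 17.4-fold higher than in immature pools (limma adjusted p = 0.006). The bound was 10.7-fold without mature pool 4 and 32.2-fold without mature pool 3. With normexp background correction, whose offset of 50 compresses folds of dim spots, its fitted difference was 3.56-fold with a limma adjusted p of 0.1. Over the other alternatives its limma adjusted p lay between 0.0011 and 0.024.

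The fall in P_eeel_c19208 was the largest fitted difference of either direction in the comparison of all 8 pools. It went from 6.76 ± 1.29 in immature to -3.04 ± 2.45 in mature pools (SD, n = 4 each), a log2 difference of -9.80 (SE 1.14) or 891-fold, with a limma adjusted p of 0.0043. In immature pools 1 to 3 its processed signal was 36000, 36300 and 35800, and in immature pool 4 it was 5340. In mature pools 1 to 4 it was 181, 8.84, 21 and 8.16, and it was well above background in only 2 of them, pools 1 and 3. The difference was 182-fold with normexp, 1585-fold with array weights, 568-fold without mature pool 4, 580-fold without mature pool 2, 1380-fold without immature pool 4 and 1872-fold without mature pool 1. Its sequence is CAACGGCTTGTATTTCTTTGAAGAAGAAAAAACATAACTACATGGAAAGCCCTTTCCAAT. The probe N_eeel_c16795 went from 3.60 ± 1.64 in immature to -5.58 ± 2.19 in mature pools (SD, n = 4 each), a fitted log2 difference of -9.18 (SE 1.12), with a limma adjusted p of 0.0045. It was well above background in 1 of 4 mature pools, pool 1, so the size of this difference rests on 3 spots near the floor. With these spots raised to the floor of their arrays the difference was 205-fold, and 358-fold without immature pool 4. Without mature pool 1, no mature pool was well above background, and the difference was at least 300-fold. With normexp, whose offset compresses folds of dim spots, it was 32.9-fold. Its sequence is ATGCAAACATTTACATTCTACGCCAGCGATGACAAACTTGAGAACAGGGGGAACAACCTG. Both probes were lowest among the immature pools in pool 4 and highest among the mature pools in pool 1.

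**Figure D2:**
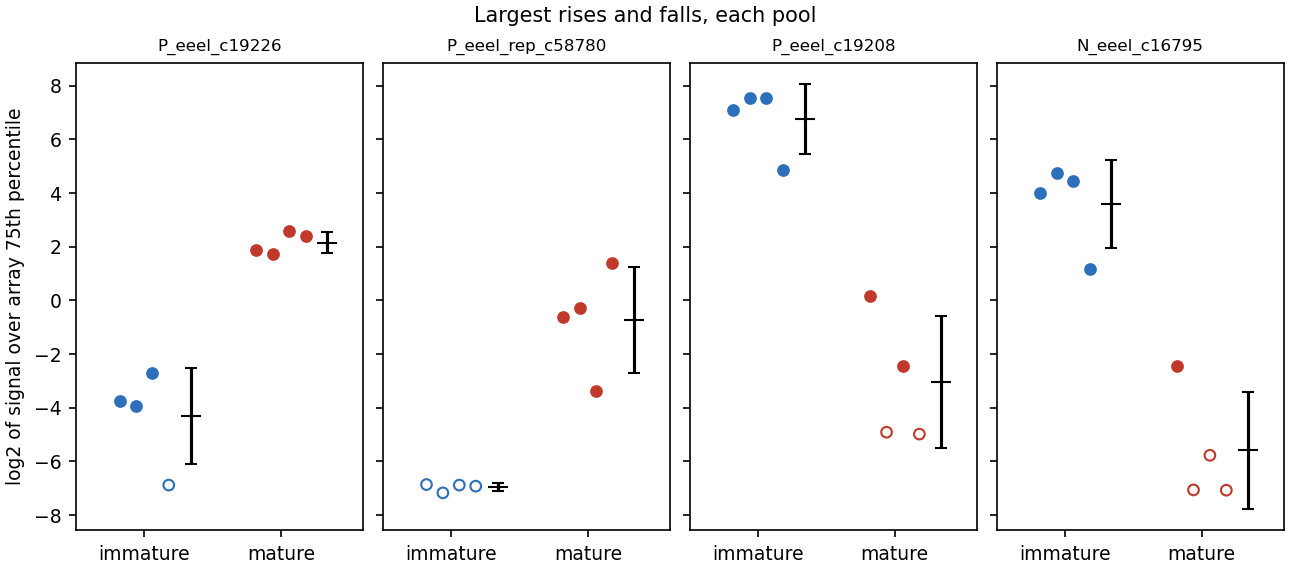
The levels of the 4 named probes in each pool are given as log2 of signal over the 75th percentile of the array, with filled points for spots well above background, open points for the others, and bars for the mean and SD (n = 4). The probe P_eeel_c19208 lay between 4.85 and 7.55 in immature pools and between -4.98 and 0.18 in mature pools.

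Some probes passed the detection limit in 1 group alone, which does not show that their transcripts were absent from the other group. On the arrays, 27 probes were well above background in every immature pool and in no mature pool, and 8 probes were so in every mature pool and in no immature pool. Of the 27 probes, 10 passed the limma threshold as lower in mature males. Over the 27, the bounds had a minimum of 1.08-fold, a median of 1.61-fold and a maximum of 17.1-fold. Fewer probes were well above background in mature pools (56.3% against 59.5%), which may add to this count. Of the 8 probes, 7 passed as higher in mature males, with a median of at least 5.76-fold and a maximum of at least 22.1-fold over the 8. A bound of at least 2-fold was reached by 8 of the 27 and by 7 of the 8. With 1 pool left out, the counts lay between 32 and 49 and between 8 and 14. The 22 probes past the threshold with no array well above background in their lower group comprised 10 higher and 12 lower in mature males.

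The array carried a pair of probes, with names beginning S and AS, for each of 1390 contigs, and the files do not explain these prefixes. Both probes of a contig were tested for 434 contigs, the S probe alone for 485 and the AS probe alone for 184. Between the S and AS probes of the 434 contigs, differences between mature and immature males had Pearson's r = 0.454 and Spearman's rho = 0.403. These correlations are across contigs, which are not independent replicates, and both probes were read in the same 8 pools. Over the 34 other splits of the arrays into 4 and 4, r on the same contigs lay between 0.139 and 0.422 (median 0.288) and rho between 0.0946 and 0.437 (median 0.263). The rho of the real split did not exceed that range. With normexp r was 0.294. In 27 contigs at least 1 probe of the pair passed the threshold: 16 with the S probe alone, 10 with the AS probe alone and 1 with both, in the same direction. In 11 of these contigs both probes had been tested, and 9 of the 11 had the same sign in both. Whether the S and AS probes of a contig differed in their response was not tested.

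**Figure D3:**
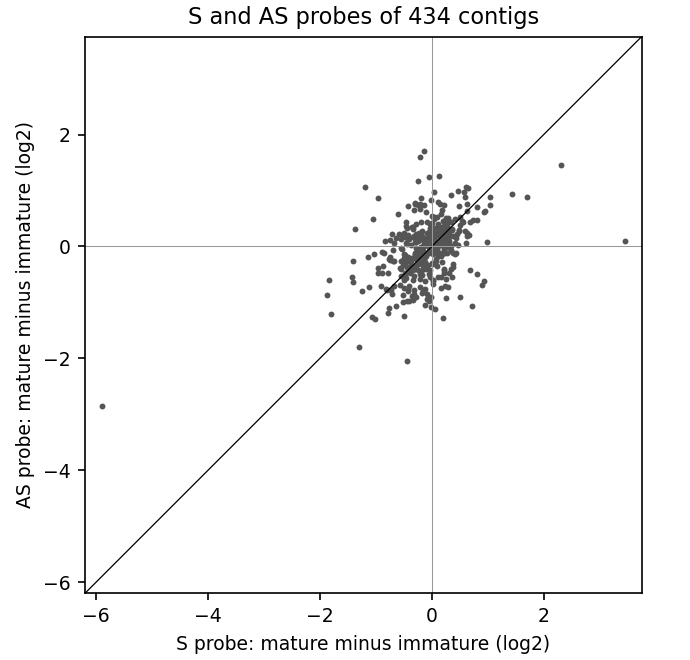
Each point is 1 of 434 contigs with mature minus immature (log2) of its S probe on the horizontal and of its AS probe on the vertical axis, and the diagonal marks equal differences. The scatter around the diagonal is wide, and r was 0.454 across contigs, against up to 0.422 in other splits of the same arrays. Spearman's rho was 0.403, against up to 0.437 in other splits. The lowest values of both probes came from 1 contig (-5.89 for S, -2.85 for AS), and r without it was not computed.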

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

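The splits of the arrays, the placement of calls on the array and the leaving out of single arrays were planned before the results they measure were seen, and the tests of the slide rows, of mixed or shared RNA and of the spike-in curve were chosen afterwards. Among 16 sets of 4 pools examined for a pool far from the others, 2 had one. Chance gives about 1 in 20 sets, so 2 among 16 can arise by chance. The probe P_eeel_c19208 was at 4.85 in immature pool 4 and between 7.10 and 7.55 in the other immature pools. The gap made up 0.832 of the range, above the critical value of Dixon's test. The log2 75th percentile of the signal, before scaling, was 8.04 in immature pool 1 and between 7.53 and 7.61 in the other immature pools, a gap of 0.834 of the range.

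The difference between mature and immature livers exceeded every other division of the arrays. Of the 35 splits of the 8 arrays into 4 and 4, only 1, the real one, gave as many as 184 probes, and the highest of the others gave 2. The same held for differences of at least 2-fold, with 161 probes against 2. These counts argue against chance only as far as 35 splits allow, since the real split can at best be 1 of 35. Every other split mixes the groups, which adds their difference to its spread and lowers its count. The contrast with 2 probes is therefore partly built in. A damaged area is argued against by 10 adjacent pairs of called spots, where 10000 random placements had a median of 8 and a 95th percentile of 13 (permutation p = 0.33). Row of the slide and maturity cannot be told apart, since 0 rows held arrays of both groups. The response of the liver to hCG and maturation remains open beside that position effect.

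Immature pool 4 and mature pool 1 lay nearest to the opposite group in both P_eeel_c19208 and N_eeel_c16795. Immature pool 4 would need 83% and 89.6% of mature RNA to give its values, but over the 86 probes higher in mature males in a fit without that pool it reached a median of 2.01% of the mature level (quartiles -2.87% and 18.6%), which argues against mixed RNA. A trace of 0.62% to 0.80% of immature RNA in mature pool 1 would give its values, and this stays open because 0 other probes lower in mature males were low enough to show it. Deviations of both probes from their group means went together over the 8 pools (Pearson's r = 0.969, exact permutation p = 0.0052, Spearman's rho = 0.929, exact permutation p = 0.0035). The 8 include the displaced pools that prompted this test, so these p-values restate that pattern and give no independent support. Over the 6 other pools r was 0.951 (exact permutation p = 0.083). Both correlations include floor spots. In mature pools 2 to 4, N_eeel_c16795 was not well above background, with signals of 2, 2.1 and 1.92. Its scaled values there, -7.06, -5.77 and -7.07, differed mainly through the 75th percentile of each array. Whether both probes may read 1 transcript or share a cause therefore cannot be told apart from chance or scaling beyond the displaced pools. Males that differ in their stage of maturation within a group are a biological candidate without a test of its own: of 76 other lower probes, immature pool 4 was lowest of its group in 46 (60.5%) and mature pool 1 highest in 16 (21.1%), where an even share is 25%, but immature pool 4 was nearest to mature males in only 27 of 106 higher probes (25.5%), and 0 of 182 other called probes had r over 0.9 with both.

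Relative to the other tested probes, the 877 brightest were at -0.28 on the log2 scale in mature minus immature males without passing the test (SE 0.13, exact permutation p = 0.0857). The brightest spike-in controls minus the dimmer ones also differed, by -0.072 (exact permutation p = 0.0286, the smallest possible), so some compression of bright signals may contribute. After a spike-in curve the gap was -0.21 (exact permutation p = 0.171), within 2 SE of 0, so compression as the whole cause cannot be told apart from a shift in abundant transcripts. The gap was -0.007 with quantile normalization and -0.014 with the deposited table, which make the arrays' distributions nearly alike, and -0.436 with no filter. A single array is argued against, since the gap closest to 0 was -0.17, without immature pool 2.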

How the results depend on the processing

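Spike-in scaling and curve, the slide column as a block, averaging of identical sequences, the second detection flag and leaving out pools for the counts of probes detected in 1 group alone were chosen after seeing the data. The 184 probes past the threshold became 102 with normexp, 104 with no filter, 121 with probes found on all arrays, 503 with array weights, 80 with spike-in scaling and 105 with the slide column as a block. Array weights kept 183 of the 184 and gave the lowest weight, 0.35, to mature pool 3. The other alternatives that kept all pools gave 154 to 225. The 161 probes with at least a 2-fold difference became 89 with normexp, 104 with no filter, 291 with array weights, 80 with spike-in scaling and 105 with the block. Leaving out 1 pool gave 100 to 172 and 100 to 158 probes, from fewer samples. The first count moved by over 1.5 times without immature pool 1 (121), 2 (111) or 3 (117) or mature pool 1 (103) or 2 (100), and the second without mature pool 1 (103) or 2 (100). The share of higher probes, 57.6%, ran from 51.3% with array weights to 68.5% without immature pool 2, with 52.8% without immature pool 4 and 66.5% with the spike-in curve. The gap in mean correlation within and between groups, 0.0138, was 0.00573 with no filter and 0.0132 to 0.0163 with 1 pool left out. Beyond fewer samples, the cause was not tested.

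For probes detected in immature pools alone, 27 became 32 to 49 with 1 pool left out, since fewer arrays must meet the rule, with 44 without immature pool 3, 49 without immature pool 4, 49 without mature pool 2 and 42 without mature pool 4. For mature pools alone, 8 became 8 to 14, with 13 without immature pool 1, 14 without immature pool 2, 13 without immature pool 4 and 13 without mature pool 3. With the second detection flag the counts were 20 and 6. Over 80 values of the 4 named probes, 79 kept their direction and stayed past the threshold, and P_eeel_rep_c58780 with normexp (1.83, limma adjusted p = 0.1) kept its direction alone. The filter on probes above background on all arrays removed all 4. With normexp the log2 differences shrank from 6.47 to 3.66 for P_eeel_c19226, from -9.80 to -7.51 for P_eeel_c19208 and from -9.18 to -5.04 for N_eeel_c16795. The offset of 50 added to each signal shrinks differences of dim spots by itself, so part of this change is built in. The correlation of S and AS differences, 0.454, was 0.294 with normexp, 0.378 with probes above background on all arrays, 0.536 with probes found on all arrays, and 0.409 to 0.499 with 1 pool left out. Slide and scan date as blocks, tests per gene and tests of gene lists were not run. No paired analysis by replicate number was possible because the labels share no numbers between the groups. The slide column block paired arrays by position. Signal over background limited tests to 58.8% of probes.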

Other observations

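These values, and the choice to look at them, came after the results were seen. Immature pool 4 was the immature pool nearest to the mature males in 48 of the 78 probes lower in mature males (61.5%), where an even share is 25%. The 78 include P_eeel_c19208 and N_eeel_c16795, which prompted the look. This count therefore repeats the one given above for the 76 other lower probes and is no separate evidence. In the 106 probes higher in mature males immature pool 4 was nearest in 27 (25.5%). For the other immature pools the shares among the lower probes were 11.5%, 8.97% and 17.9%. Among mature pools the shares nearest to immature males lay between 16.7% and 30.8% for the lower probes and between 17% and 33% for the higher ones. No test of these shares was made, since the probes of a pool are not independent.

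Among tested probes, the share past the threshold was 2.08% for names beginning P, 2.4% for N, 1.85% for S and 1.78% for AS. Of the called probes with names beginning P, 74 were higher and 39 lower in mature males, and of those beginning N, 21 were higher and 22 lower. Whether these splits differed was not tested.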
